A study of Homo sapiens with 12 samples.

How the data were processed

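RNA was measured by sequencing in 12 libraries of the ovarian cancer cell line OVCAR8, 3 cultures in each of 4 groups. Per the labels, total RNA was taken at 70% confluency, 500 ng entered a stranded total RNA kit that removes ribosomal RNA, and 12 cycles of PCR followed. The replicate numbers only follow the order of the samples, so no pairs were formed from them. The labels give no batch, plate or date, so none could be tested.

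The authors quantified transcripts with Salmon 0.10.2 against the human genome build hg38. The deposited files hold expected counts per transcript, which are not scaled between libraries. They also hold TPM, which per the file headers is scaled to the same sum within each library. The length and effective length of each transcript, in bases, are the other values per the file headers. The annotation release, the library type and any bias correction are not stated in the notes that go with the files. Of 199658 transcripts, 199368 (99.85%) matched GENCODE release 29, which supplied gene symbols and positions. The 290 others held from 0.0153% to 0.0551% of the reads of a library and were left out.

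Expected counts were summed per gene symbol, giving 56242 symbols from 57722 gene identifiers, and rounded. Of these symbols, 166 carry more than 1 identifier. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 18988 genes. Library sizes were scaled with TMM factors, and CPM are counts relative to that scaled library size. All 12 libraries entered 1 fit with a term per group. Each of 6 pairs of groups, and the mean of the 3 clones against the parent, was compared with the edgeR quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The common dispersion corresponded to a coefficient of variation of 12.1% between cultures. Every adjusted p measures the spread between cultures of the same clone, not between clones. Expected overlaps between comparisons are the product of the numbers called over the number tested, and the effect of the shared parent libraries was simulated in groups without any changed gene.

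The 38 gene lists, the named genes, the comparisons and all but 2 of the alternatives were fixed before the data were examined. Lists with at least 3 genes tested were compared with all other genes by camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists of a comparison. Each list was tested again with a correlation estimated from its own genes, and the counts within a list were also adjusted over the list alone.

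Named genes followed a rule. It always names 11 regulators of entry into mitosis, drug efflux and cell cycle arrest. It names the 12 genes with the largest rise and the 12 with the largest fall among those called the same way in the 3 clones, ranked by the smallest change over the clones. For each pair of groups it names the 5 with the largest rise and the 5 with the largest fall. Genes of these last 2 kinds reach a mean of at least 5 CPM in a group, for pairs in 1 of the 2 groups compared, and the libraries of the groups compared do not overlap, so a change stated for them holds in every library. From each list it names up to 4 called members with the largest log2 change in size. It adds up to 2 with the largest change among those that moved against the rest. Any other gene is said to have been chosen after its values were seen.

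Errors of log2 changes are standard errors (SE) and errors of CPM are standard deviations (SD) over 3 cultures. Where a group held 0 reads of a gene, a bound was computed from a floor of 3 counts over the group. Intervals of shares are exact Clopper-Pearson intervals at 95%, and like the floor they cover counting error only, since PCR copies were not told apart.

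The alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, protein-coding genes alone, summing per gene identifier, an offset for mean transcript length, a fit of only the groups compared, a 2-fold minimum, each library left out in turn, and for lists an estimated correlation and the fry test. Chosen after the data were seen were a fit without clone 2 replicate 3 and clone 4 replicate 3, and a fit without the genes that took most reads of clone 2 replicate 3. Counts were compared with those of the 10 splits of the 6 libraries of a pair of groups, or of 100 regroupings of all 12 libraries. Positions along the genome were summarised as the median log2 change in windows of 10 Mb with at least 15 genes. The window length and the size that counts as shifted were chosen after window medians had been seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

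The methods were tested on simulated data built from the library sizes and spread of these libraries. For clone 3 against parent, edgeR recovered 40.3% of simulated log2 changes of 0.5, 70.1% of 1 and 90.9% of 2, with 5.6% of its calls false. DESeq2 recovered 49.3%, 71.6% and 90.9%, with 16.6% false. For clone 3 against clone 2, edgeR recovered 38.8%, 65.7% and 87.9%. Camera called 3 of 3 shifted lists and 1 of 30 others. Genes were drawn independently of each other there, so this gives no rate of false calls for lists of correlated genes.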

Results

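RNA was sequenced from 12 cultures of OVCAR8, an established cell line of high-grade serous ovarian cancer, in 4 groups of 3. The parent line was treated with 100 nM AZD1775, an inhibitor of the kinase Wee1, for 24 h. The other groups are clones 2, 3 and 4, which were picked as single colonies of OVCAR8 under AZD1775, resist 300 nM of it and were kept in it. No parent culture without the drug is among these samples, so dose and time under drug differ between clones and parent together with resistance. The comparisons ask which genes differ between resistant clones and the treated parent, which of these differences the clones share, and how the clones differ from each other.

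Totals ranged from 34129724 to 64695240 estimated reads in 11 libraries and reached 25090553 in clone 2 replicate 3. In that library 70.97% of the reads (95% interval 70.95% to 70.99%) fell on 2 genes with 18S rRNA sequence, against 0.00203% to 0.0805% in the others. Nuclear protein-coding genes took 25% of its reads and 84.3% to 86.4% of those of the others. Across 9790 genes, the log2 CPM of 2 cultures of the same group correlated at 0.9959 to 0.9979, except for pairs with clone 2 replicate 3 (0.9333 and 0.9473) and with clone 4 replicate 3 (0.9849 and 0.9863). Genes are not independent replicates. The first principal component (45.3% of the variance) placed clone 4 at −26.6 to −25.6, the parent at −10.4 to −8.62, clone 2 at 11.6 to 23 and clone 3 at 19.1 to 20.8.

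**Figure D1:**
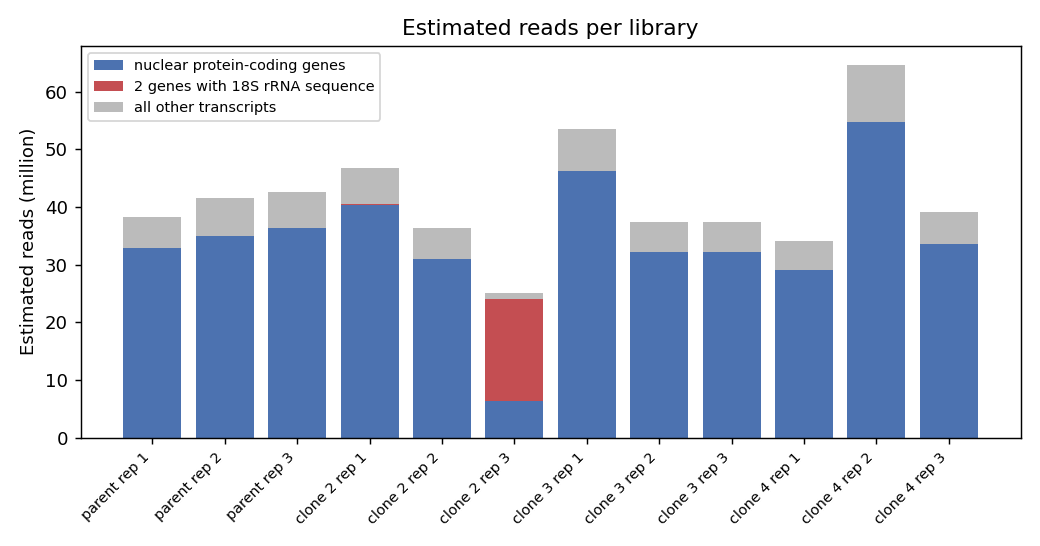
Estimated reads of each library as stacked bars for nuclear protein-coding genes, 2 genes with 18S rRNA sequence and all other genes. Protein-coding genes hold 25% of the reads of clone 2 replicate 3 and 84.3% to 86.4% of those of the other 11 libraries.

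The largest rises shared by the clones included CPT1A, GNG4 and SRGN, and the largest shared falls APOE, MFAP5, PALLD and ANXA8. CPT1A (chromosome 11, 68754620 to 68844410, GRCh38), which brings long-chain fatty acids into mitochondria, rose from 2.24 ± 0.343 CPM (SD, n = 3) in the parent to 8.24, 7.37 and 10.8 CPM in clones 2, 3 and 4. The mean log2 change over the clones was 1.96 ± 0.12 (SE, adjusted p = 4.37e-07). ACSS1, a mitochondrial acetyl-CoA synthetase, rose by 1.77 ± 0.28 (adjusted p = 0.000873) and GPAT3, an enzyme of triglyceride synthesis, by 1.53 (adjusted p = 2.22e-06). GNG4, a G protein subunit, rose from 5.60 CPM to 30.9, 12.6 and 16.8 CPM, and SRGN, the proteoglycan serglycin, from 26.0 CPM to 82.3, 78.8 and 63.3 CPM (mean log2 change 1.52 ± 0.08, adjusted p = 2.88e-07). Others with a large shared rise included LINC01204 (2.98), TMEM158 (2.28), GLB1L2 (1.95), ARFGEF3 (1.82), HTRA1 (1.73) and IL17RB (1.40). APOE, a carrier of lipids, fell from 20.4 CPM to 2.53, 0.713 and 9.47 CPM (−2.95 ± 0.11, adjusted p = 1.03e-08). MFAP5, a protein of matrix microfibrils, fell from 48.3 CPM to 10.5, 10.1 and 22.1 CPM (−1.86 ± 0.10, adjusted p = 1.53e-07). PALLD, an actin-associated protein, fell from 33.0 CPM to 16.1, 7.30 and 11.7 CPM (−1.57 ± 0.06, adjusted p = 1.03e-08). ANXA8 fell from 142 CPM to 38.7, 10.7 and 14.4 CPM, and its near-identical copy ANXA8L1, with which it can share reads, from 31.3 CPM to 6.38, 2.28 and 2.79 CPM. The others with the largest shared fall were MYOM3 (−2.08), ACTC1 (−1.74), RCN3 (−1.72), TRPC4 (−1.61), MEF2C (−1.55, and −2.62 with the length offset), S100A2 (−1.53) and ARTN (−1.46). Each of these changes held in all 9 clone libraries against all 3 parent libraries.

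Of the 18988 genes tested with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 981 were called in each clone against the parent. Of these, 628 changed the same way in the 3 clones (310 higher, 318 lower), where independent calls would give 23 and 27. Simulated groups that share the parent gave at most 0, but no gene was changed in them, so few calls could arise. How much of the 628 comes from the shared parent libraries is therefore not shown. The other 353 of the 981 changed in opposite directions, and 106 of the 628 changed at least 2-fold in each clone. The mean of the clones differed from the parent for 3849 genes (1721 higher, 2128 lower), 486 of them by at least 2-fold (283 higher, 203 lower). Without parent replicate 1, 2 or 3 the shared count was 341, 369 or 356 and the count for the mean 2201, 2213 or 2336. The shared count was 1092 without clone 2 replicate 3 and 375 with an offset for transcript length. Without both clone 2 replicate 3 and clone 4 replicate 3 the counts were 1591 and 7284.

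WEE1, which encodes the kinase that AZD1775 inhibits, was higher in each clone. Its level (chromosome 11, 9573681 to 9593457) was 36.3 ± 0.835 CPM (SD, n = 3) in the parent and 47.1 ± 7.77, 45.1 ± 1.01 and 48.2 ± 2.49 CPM in clones 2, 3 and 4, with a mean log2 change of 0.36 ± 0.08 (SE, adjusted p = 0.00572). All 9 clone libraries lay above all 3 parent libraries. Clone by clone, the log2 change of WEE1 was 0.36 ± 0.09 (adjusted p = 0.0168), 0.31 ± 0.09 (adjusted p = 0.0249) and 0.41 ± 0.09 (adjusted p = 0.00799). PKMYT1, the related kinase that also restrains CDK1, rose in clone 3 (0.33 ± 0.08, adjusted p = 0.00668) and had log2 changes of 0.04 in clone 2 (adjusted p = 0.756) and 0.17 in clone 4 (adjusted p = 0.163). CCNB1, the cyclin B that activates CDK1 for entry into mitosis, fell from 548 ± 19.7 CPM to 359 ± 47.1 CPM in clone 2 and 289 ± 15.5 CPM in clone 3. It stood at 466 ± 52.6 CPM in clone 4 (log2 change −0.23, adjusted p = 0.124). There replicates 1 and 2 lay at 429 and 443 CPM and replicate 3 at 526 CPM, against 526 to 563 CPM in the parent. CDC25C, a phosphatase that removes the marks Wee1 places, fell from 34.7 ± 1.58 CPM to 20 ± 2.24 and 14.2 ± 0.226 CPM in clones 2 and 3, and stood at 38.4 ± 4.52 CPM in clone 4 (0.15, adjusted p = 0.32). CDC25B fell in clones 2 (−0.44, adjusted p = 0.0262) and 3 (−0.40, adjusted p = 0.0315) and CDC25A in clone 2 (−0.27, adjusted p = 0.0139). CDK1 fell in clone 3 (−0.41, adjusted p = 0.0477) and had log2 changes of −0.33 in clone 2 (adjusted p = 0.123) and 0.15 in clone 4 (adjusted p = 0.532). Replicates 1, 2 and 3 lay at 139, 139 and 186 CPM in clone 2 and at 186, 185 and 269 CPM in clone 4. The parent lay at 189 to 198 CPM. Replicate 3 of clones 2 and 4 correlated less well with its group, as given above. CCNE1, cyclin E1, rose in clone 3 from 19.6 to 31.8 CPM (0.70 ± 0.17, adjusted p = 0.00797), as did CDKN1A, the CDK inhibitor p21, from 13.1 ± 0.152 to 25.6 ± 1.21 CPM (0.97 ± 0.16, adjusted p = 0.0006). CHEK1, the checkpoint kinase, had log2 changes of 0.22, 0.05 and −0.04, none called. ABCB1, a drug efflux pump, rose in clone 4 from 6.39 ± 0.375 to 11.1 ± 0.192 CPM (0.80 ± 0.12, adjusted p = 0.000441). It fell in clones 2 (−0.58 ± 0.13, adjusted p = 0.00691) and 3 (−0.91, adjusted p = 0.000167).

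The WEE1 call in clone 2 (0.36 ± 0.09, adjusted p = 0.0168) was lost without parent replicate 1 (adjusted p = 0.0598), without parent replicate 2 (0.0649), in a fit of only the 2 groups (0.0748) and with an offset for transcript length (0.0815). Its adjusted p ranged from 0.000564 to 0.0815 over the alternatives. CCNB1 and CDC25C in clones 2 and 3, and CCNE1 and CDKN1A in clone 3, were called in all 12 alternatives run for them. In the mean of the clones CDKN1A changed by 0.41 (adjusted p = 0.0472), a call lost without parent replicate 1, 2 or 3 (adjusted p of 0.138, 0.154 and 0.144). It was also lost without clone 2 replicate 1 (0.0513), without clone 3 replicate 1, 2 or 3 (0.0727, 0.0803 and 0.0667), with DESeq2 size factors (0.0518) and with the length offset (0.0759), over a range of 0.000168 to 0.154. CDC25B (−0.30, adjusted p = 0.0514), CDK1 (−0.20, adjusted p = 0.261) and CCNE1 (0.30, adjusted p = 0.164) were not called in the mean. They were without clone 2 replicate 3 and clone 4 replicate 3 (adjusted p of 1.24e-06, 1.54e-06 and 2.78e-06). For CDK1, CDC25A, CDC25B and PKMYT1 the alternatives were recorded in the mean of the clones. Only the fit without clone 2 replicate 3 and clone 4 replicate 3 was also recorded clone by clone, and those values are not given here. For WEE1 the alternatives are given here for clone 2 alone.

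**Figure D2:**
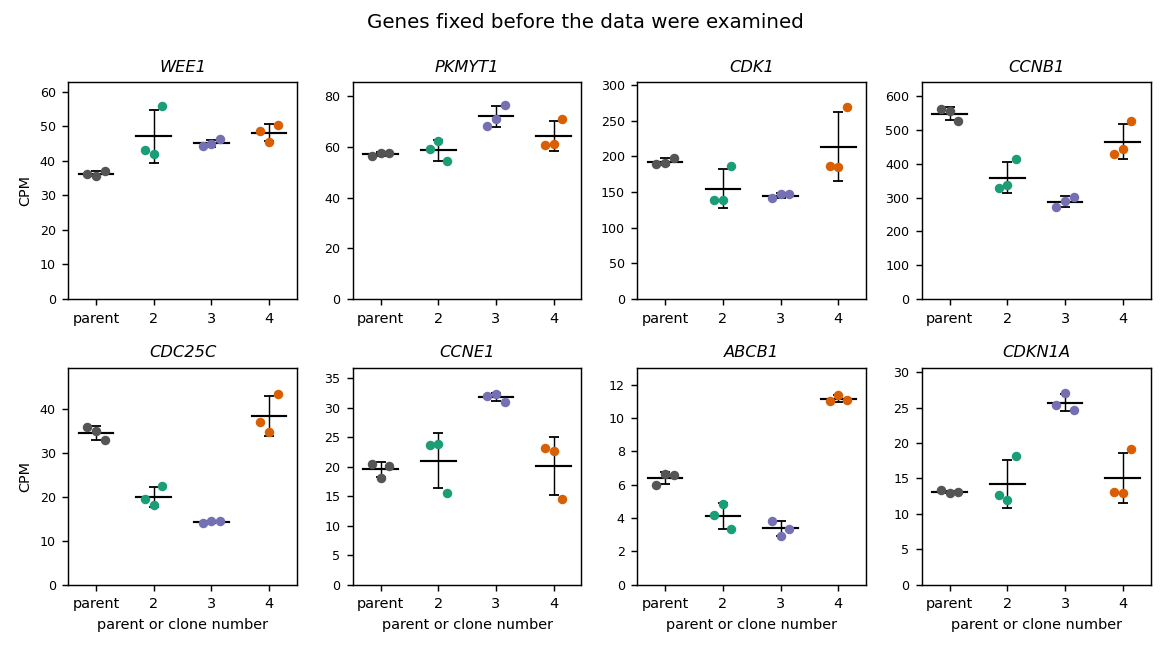
CPM of 8 genes in each library (dots) on linear axes from 0, with the mean of 3 cultures as a black bar and the SD as error bar, for the parent and clones 2, 3 and 4. WEE1 lies at 36.3 CPM in the parent and 45.1 to 48.2 CPM in the clones, and ABCB1 at 6.39 CPM in the parent and 11.1 CPM in clone 4.

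In the mean of the clones, 13 of 38 gene lists moved against all other genes. Of 100 regroupings of the 12 libraries, the real one included, 11 gave as many, with a median of 9 over the others. A random division of the libraries thus cannot be excluded for this count. Inflammatory targets of NF-κB led, with 20 of 26 members higher and none lower (23 and 0 adjusted over the list alone). The NF-κB list had adjusted p = 2.45e-39, and adjusted p = 0.00171 with an estimated correlation. In clone 4 against the parent it fell (adjusted p = 6.27e-13, and adjusted p = 0.149 with an estimated correlation). Of 35 replication-dependent histone genes, 23 rose and 1 fell (31 and 1 adjusted over the list alone). The histone list had adjusted p = 2.41e-08, and adjusted p = 0.717 with an estimated correlation. Of the 35, 33 were lower in clone 2 replicate 3 (median −0.44) and 0 in clone 4 replicate 3 (median 0.37) than in the other libraries of their clones. Without both, 33 rose and 1 fell (adjusted p = 1.23e-20, and adjusted p = 0.319 with an estimated correlation). DNA replication genes rose in 14 of 42 cases and fell in 2 (18 and 2 adjusted over the list alone). Among them were E2F2, a transcription factor of S phase entry (0.88, adjusted p = 0.000184), and MCM6, a subunit of the replicative helicase (0.59, adjusted p = 0.00284), whereas TK1, thymidine kinase, fell (−0.53, adjusted p = 0.00172). The replication list had adjusted p = 0.000593, and adjusted p = 0.717 with an estimated correlation. In clone 2 replicate 3, 33 of the 42 were lower than in the other libraries of its clone. Without it and clone 4 replicate 3, 30 rose and 3 fell (adjusted p = 1.42e-07, and adjusted p = 0.491 with an estimated correlation). Of 40 mitosis genes 10 fell and none rose (10 and 0 adjusted over the list alone), with the kinesins KIF20A (−0.76, adjusted p = 1.16e-05) and KIF2C (−0.43) and the survivin gene BIRC5 (−0.41). The mitosis list had adjusted p = 0.00169, and adjusted p = 0.751 with an estimated correlation. Among 22 genes of Wee1 and CDK1 control of mitosis, 3 rose and 7 fell (5 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.189, and adjusted p = 0.751 with an estimated correlation). Without clone 2 replicate 3 and clone 4 replicate 3 the members called were 12 lower and 6 higher in this list (adjusted p = 0.00177, and adjusted p = 0.233 with an estimated correlation). In the mitosis list 37 were then lower and 1 higher (adjusted p = 8.81e-16, and adjusted p = 0.201 with an estimated correlation).

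Of 36 subunits of oxidative phosphorylation, 12 fell and none rose (13 adjusted over the list alone), such as UQCRB (−0.55 ± 0.04, adjusted p = 5.36e-06), UQCRC1 (−0.59) and COX6C (−0.53). The respiratory list had adjusted p = 0.00139, and adjusted p = 0.73 with an estimated correlation. Against the other libraries of their clones, 32 of the 36 were lower in clone 2 replicate 3 (median −0.31) and 30 in clone 4 replicate 3 (−0.11). Without both libraries the median in clone 2 went from −0.19 to −0.09 and the list in the mean of the clones had adjusted p = 0.00281, and adjusted p = 0.763 with an estimated correlation. Hypoxia and glycolysis genes fell in 12 of 28 cases and rose in 3 (14 and 4 adjusted over the list alone). Examples are ANKRD37 (−1.36, adjusted p = 8.85e-05) and the enolase ENO2 (−0.71, adjusted p = 3.43e-06), which fell, and the peptide hormone gene ADM, which rose (1.02, adjusted p = 0.00102). The hypoxia list had adjusted p = 0.0261, and adjusted p = 0.717 with an estimated correlation. That list was not called without clone 4 replicate 1 (adjusted p = 0.0562). Stress genes under ATF4 rose in 7 of 33 cases and fell in none (7 adjusted over the list alone), including the amino acid transporter SLC1A4 (1.24, adjusted p = 0.00276) and the hormone gene STC2 (0.78, adjusted p = 0.00233). The ATF4 list had adjusted p = 0.00339, and adjusted p = 0.751 with an estimated correlation. Without clone 2 replicate 3 and clone 4 replicate 3, in which this list was low, 28 members were higher (adjusted p = 6.62e-20, and adjusted p = 0.145 with an estimated correlation). Of 26 apoptosis regulators 9 rose and 1 fell (10 and 1 adjusted over the list alone). Among those that rose were BIRC3, an inhibitor of apoptosis and NF-κB target (2.18 ± 0.15, adjusted p = 1.36e-06), and BCL2L11, which promotes it (0.92 ± 0.19, adjusted p = 0.00429). The apoptosis list had adjusted p = 0.00543, and adjusted p = 0.0664 with an estimated correlation.

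Among markers of other cell types, 3 of 4 fibroblast genes fell (3 adjusted over the list alone). The fibroblast list had adjusted p = 7.96e-07, and adjusted p = 0.011 with an estimated correlation. That last call was lost without clone 2 replicate 3 and clone 4 replicate 3 (adjusted p = 1.14e-05, and adjusted p = 0.0916 with an estimated correlation). COL1A1, a collagen, lay at 116 CPM in the parent and 82.8, 21.3 and 124 CPM in clones 2, 3 and 4 (mean log2 change −0.95, adjusted p = 3.83e-05). LUM, another matrix gene, lay at 1.27 CPM in the parent and 0.00606, 0.0212 and 0.112 CPM in the clones. Of 5 mesothelial genes 3 fell (4 adjusted over the list alone), with the desmin gene DES at −2.02 ± 0.15 (adjusted p = 2.76e-06). The mesothelial list had adjusted p = 0.00125, and adjusted p = 0.0623 with an estimated correlation. Of 7 serous ovarian markers, 3 rose and 1 fell (3 and 2 adjusted over the list alone, adjusted p = 0.146). EPCAM, an epithelial adhesion molecule, rose in each clone (0.83, 1.08 and 0.76). The keratin gene KRT7 lay at 754 CPM in the parent and 426, 251 and 485 CPM in the clones (mean log2 change −1.02, adjusted p = 0.000138). PAX8, a Müllerian lineage factor, rose in clones 2 (1.04, adjusted p = 1.42e-06) and 3 (1.08, adjusted p = 4.19e-07) and fell in clone 4 (−0.71, adjusted p = 2.28e-05). PTPRC, the common leukocyte antigen, lay between 0.22 and 0.327 CPM in every group.

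3 other lists lay close to the threshold in the mean of the clones, and all were lost with an estimated correlation. MAPK output genes (4 of 22 higher, 1 lower, 6 and 3 adjusted over the list alone) included TGFA, an EGFR ligand, at 1.46 ± 0.07 (adjusted p = 4.67e-08). The MAPK list had adjusted p = 0.0307, and adjusted p = 0.717 with an estimated correlation. Its call was lost without parent replicate 2 (adjusted p = 0.0681), without clone 2 replicate 3 (0.155), without it and clone 4 replicate 3 (0.2) and with the length offset (0.22). WNT targets (5 of 18 higher, none lower, 5 adjusted over the list alone) were not called without parent replicate 1 (adjusted p = 0.0555), with the length offset (0.223) or among protein-coding genes alone (0.0638). The WNT list had adjusted p = 0.0412, and adjusted p = 0.21 with an estimated correlation. Immediate early genes (3 of 22 higher, 1 lower, 4 and 1 adjusted over the list alone), among them KLF4 at 1.04 ± 0.09 (adjusted p = 8.12e-06), were not called without parent replicate 1 (0.0552), clone 2 replicate 3 (0.0635), clone 4 replicate 3 (0.0715) or both of these (0.118), or among protein-coding genes alone (0.0638). The early gene list had adjusted p = 0.0445, and adjusted p = 0.717 with an estimated correlation.

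In clone 2 inflammatory cytokines were among the largest rises of genes that reach 5 CPM. IL1A, the cytokine interleukin 1 alpha, rose from 1.80 ± 0.203 to 42.7 ± 12.3 CPM (log2 change 4.58 ± 0.22, adjusted p = 8.81e-08). IL1B rose from 2.73 to 60.2 CPM (4.47 ± 0.25, adjusted p = 2.66e-07) and the chemokine gene CXCL1 from 1.5 to 26.1 CPM (4.08, adjusted p = 5.13e-08). Of 26 NF-κB targets 22 rose and none fell (23 and 0 adjusted over the list alone), with a median log2 change of 1.65. The NF-κB list had adjusted p = 6.28e-89, and adjusted p = 9.24e-05 with an estimated correlation. DCDC2, a microtubule-binding protein, rose by 3.99 (adjusted p = 6.03e-07). TCEA3, a transcription elongation factor, fell from 7.12 to 0.461 CPM (−3.74, adjusted p = 4.23e-07). ATP10A, a phospholipid flippase, fell by 2.71 (adjusted p = 9.05e-06). APOE (−2.91), ANXA8L1 (−2.41) and MFAP5 (−2.18) were the others with the largest fall among genes of at least 5 CPM in clone 2 or the parent. Mitosis genes fell in 13 of 40 cases and rose in none (13 adjusted over the list alone), and DNA replication genes rose in 14 of 42 cases and fell in 3 (16 and 3 adjusted over the list alone). The mitosis list had adjusted p = 0.000413, and adjusted p = 0.772 with an estimated correlation. The replication list had adjusted p = 0.0111, and adjusted p = 0.761 with an estimated correlation. Clone 2 replicate 3 departed from its clone in both lists (medians of 0.41 for mitosis and −0.24 for replication). Without it and clone 4 replicate 3, 37 mitosis genes fell and 1 rose in clone 2 (adjusted p = 1.07e-18, and adjusted p = 0.173 with an estimated correlation). Of the replication genes 29 then rose and 5 fell (adjusted p = 1.02e-06, and adjusted p = 0.509 with an estimated correlation).

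In all, 4131 genes differed between clone 2 and the parent by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (1987 higher, 2144 lower), 773 of them by at least 2-fold (538 higher, 235 lower). Without parent replicate 1 or 2 the count was 2613 or 2679, in a fit of only the 2 groups 2707, and without clone 2 replicate 3 and clone 4 replicate 3 7175. STUM, a membrane protein, also passed the rule (7.53 ± 2.05, adjusted p = 0.0202). It lay at 63.1 CPM in clone 2 replicate 3 and at 0.255 and 0.247 CPM in replicates 1 and 2, and without replicate 3 its log2 change was 1.34 (adjusted p = 0.264). Its call was also lost without parent replicate 1, 2 or 3 (adjusted p of 0.0755, 0.0663 and 0.0765) and in a fit of only the 2 groups (0.102).

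In clone 3 inflammatory genes were again among the largest rises. IL13RA2, a decoy receptor for interleukin 13, rose from 0.26 to 64.4 ± 11 CPM (7.95 ± 0.26, adjusted p = 1.51e-09). SERPINB2, an inhibitor of plasminogen activators, rose from 5.16 to 509 ± 30.7 CPM (6.63 ± 0.51, adjusted p = 1.56e-06), and IL1B to 205 CPM (6.23 ± 0.26, adjusted p = 9.91e-09), with CXCL1 (5.49) and IL1A (5.41) next. Of 26 NF-κB targets 24 rose and none fell (24 and 0 adjusted over the list alone), with a median log2 change of 2.29. The NF-κB list had adjusted p = 2.78e-100, and adjusted p = 7.67e-05 with an estimated correlation. TGFBI, a matrix protein induced by TGFβ, fell from 1140 ± 37.9 to 51.6 ± 13.3 CPM (−4.47 ± 0.46, adjusted p = 1.83e-05). SIM1, a transcription factor, fell from 17.3 to 0.502 CPM (−5.11, adjusted p = 1.31e-09), and APOE (−4.83), the troponin gene TNNC1 (−4.69) and TCEA3 (−4.17) fell as well. Of 27 TGFβ targets 13 fell and 2 rose (15 and 2 adjusted over the list alone), with SMAD6 (−2.12) and TGFB2 (−2.01, adjusted p = 3.4e-06) among those that fell. The TGFβ list had adjusted p = 0.00346, and adjusted p = 0.622 with an estimated correlation. Apoptosis regulators rose in 13 of 26 cases and fell in none (14 adjusted over the list alone), among them BCL2A1, a protective BCL2 relative (2.92 ± 0.24, adjusted p = 3.4e-06). The apoptosis list had adjusted p = 0.000102, and adjusted p = 0.0147 with an estimated correlation. Stress genes under ATF4 rose in 11 of 33 cases and fell in none (14 adjusted over the list alone), such as STC2 (1.69, adjusted p = 1.68e-05). The ATF4 list had adjusted p = 0.000102, and adjusted p = 0.622 with an estimated correlation. Mitosis genes fell in 15 of 40 cases (19 adjusted over the list alone), led by KIF20A at −1.32 (adjusted p = 5.43e-07). The mitosis list had adjusted p = 0.000371, and adjusted p = 0.725 with an estimated correlation. Without clone 2 replicate 3 and clone 4 replicate 3, 29 ATF4 genes rose in clone 3 (adjusted p = 4.38e-18, and adjusted p = 0.161 with an estimated correlation) and 31 mitosis genes fell and 1 rose (adjusted p = 2.29e-09, and adjusted p = 0.351 with an estimated correlation).

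In all, 4957 genes differed between clone 3 and the parent by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (2336 higher, 2621 lower), 1080 of them by at least 2-fold (620 higher, 460 lower). The count was 8682 in a fit of only the 2 groups and 8629 without clone 2 replicate 3 and clone 4 replicate 3.

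In clone 4 CCL20 and CXCL5 fell and histone genes rose. CCL20, a chemokine, fell from 2.83 to 0.0855 CPM (−5.06 ± 0.28, adjusted p = 1.61e-07) and CXCL5 from 6.06 to 0.56 CPM (−3.50 ± 0.17, adjusted p = 6.74e-08). Of 26 NF-κB targets 15 fell and 1 rose (18 and 3 adjusted over the list alone), with a median log2 change of −0.73. The gene that rose was SOD2, the mitochondrial superoxide dismutase (0.72 ± 0.06, adjusted p = 9.91e-06). The NF-κB list had adjusted p = 6.27e-13, and adjusted p = 0.149 with an estimated correlation. CPA4, a carboxypeptidase, rose from 1.41 to 18.1 CPM (3.68 ± 0.16, adjusted p = 2.19e-08). TXNIP, a regulator of glucose uptake and thioredoxin, rose from 5.03 to 54.0 CPM (3.42, adjusted p = 5.3e-08). AMIGO2 rose by 2.97 ± 0.48 on the log2 scale and by 2.18 without clone 4 replicate 3, PDE1C, a phosphodiesterase, from 6.82 to 50.4 CPM (2.89, adjusted p = 3.36e-08) and TMEM158 by 2.59. TENM2, a cell adhesion protein, fell from 22.2 to 0.265 CPM (−6.34 ± 0.29, adjusted p = 3.36e-08), SDR42E1 from 5.91 to 0.148 CPM (−5.28, adjusted p = 5.38e-09), SUN3 by 3.90 and ANXA8L1 by 3.51 on the log2 scale. Of 35 replication-dependent histone genes 32 rose and none fell (33 and 0 adjusted over the list alone), such as HIST1H2BL (0.95, adjusted p = 0.000575). The histone list had adjusted p = 4.26e-15, and adjusted p = 0.594 with an estimated correlation. Clone 4 replicate 3 was higher than the other clone 4 libraries for all 35 (median 0.37), and without it and clone 2 replicate 3 the median over the list went from 0.70 to 0.54. In the window of chromosome 6 from 20 to 30 Mb, 33 genes of the list had a median log2 change of 0.70 in clone 4, 15 other histone genes 0.74 and the 36 genes there that are not histone genes 0.01. Over all 84 genes of this window the median was 0.53, and 0.37 without the 2 libraries. YAP targets rose in 9 of 22 cases and fell in none (10 and 3 adjusted over the list alone), among them the matricellular gene CTGF (1.07 ± 0.10, adjusted p = 1.35e-05). The YAP list had adjusted p = 0.00127, and adjusted p = 0.24 with an estimated correlation. Mitosis genes rose in 2 and fell in 4 of 40 cases (0 and 2 adjusted over the list alone, adjusted p = 0.933), with a median of 0.03 and a mean of 0.03 where the test pointed down.

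In all, 3578 genes differed between clone 4 and the parent by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment (1822 higher, 1756 lower), 795 of them by at least 2-fold (318 higher, 477 lower). The count was 6301 without clone 2 replicate 3 and clone 4 replicate 3, and 15 mitosis genes were then lower and 5 higher (adjusted p = 0.0168, and adjusted p = 0.962 with an estimated correlation).

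**Figure D3:**
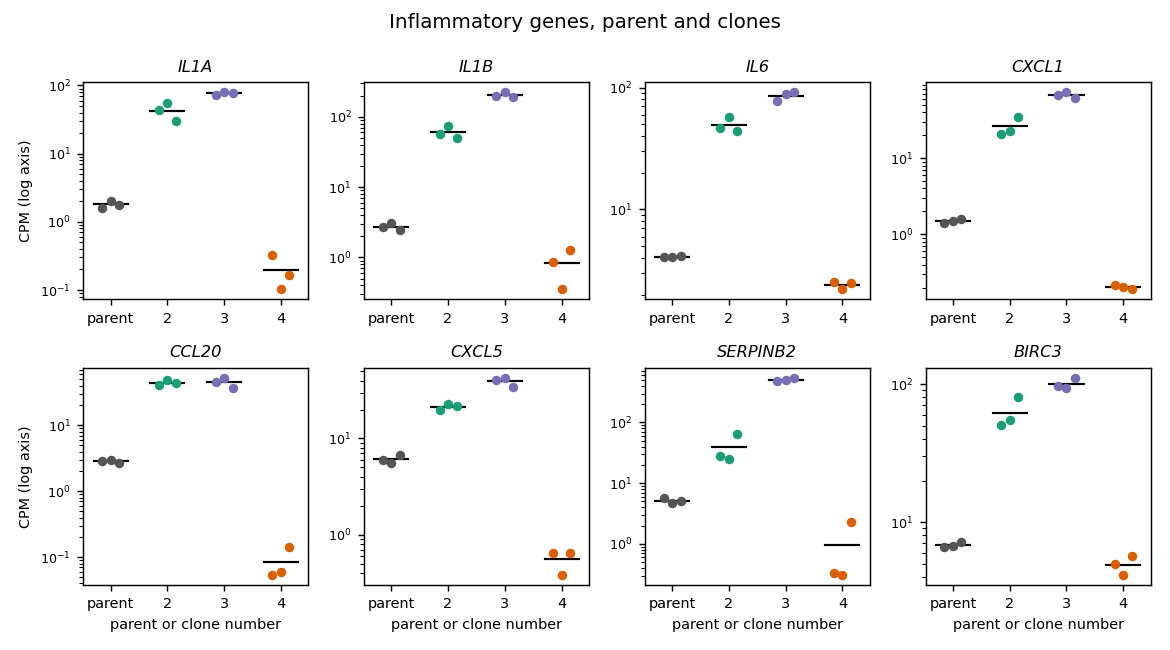
CPM of 8 inflammatory genes in each library (dots) on log axes, with the mean of 3 cultures as a bar, for the parent and clones 2, 3 and 4. IL1B lies at 2.73 CPM in the parent, 60.2 CPM in clone 2 and 205 CPM in clone 3, and CCL20 at 0.0855 CPM in clone 4.

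Clones 2 and 3 shared most of their direction of change, and clone 4 shared less with either. Of 2515 genes called in both clones 2 and 3 against the parent, 2469 (98.2%) moved the same way, where independent calls would give 244 higher and 296 lower. The log2 changes of clones 2 and 3 had a covariance of 0.129 across 11403 genes, where the shared parent libraries alone gave a covariance of 0.0111 in simulation. For clones 2 and 4, 978 of 1442 genes (67.8%) moved the same way and 464 in opposite directions (covariance 0.00225, simulated 0.0113). For clones 3 and 4 these were 997 of 1588 (62.8%) and 591 (covariance 0.00922, simulated 0.0116). Genes are not independent, and these covariances share the parent libraries. The simulation gave every group the spread of the fit of all 12 libraries, clone 2 replicate 3 included. Departures from the group had an SD of 0.108 to 0.134 in the parent and 0.588 in that library. The simulated covariances can thus be too high for the parent. They do not show whether clone 4 shares changes with clone 2 or 3 beyond the parent libraries.

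Between clones 3 and 2, IL13RA2 was higher in clone 3 by 5.38 on the log2 scale, the chaperone gene SCG5 by 4.25, SERPINB2 by 3.76, the lysosomal enzyme gene GALC by 3.69 (adjusted p = 1.01e-07) and the BMP antagonist gene GREM1 by 3.35. TENM2 (−4.88, adjusted p = 1.01e-07), SIM1 (−4.58), NEURL1 (−3.39), DCDC2 (−2.66) and TGFBI (−2.42) were lower in clone 3. NF-κB targets were higher in clone 3 in 15 of 26 cases and lower in none (18 and 0 adjusted over the list alone). The NF-κB list had adjusted p = 1.27e-12, and adjusted p = 0.127 with an estimated correlation. In all, 2551 genes differed by the edgeR quasi-likelihood test (1178 higher, 1373 lower in clone 3), 376 by at least 2-fold (145 higher, 231 lower). The count was 1491, 1394 or 1448 without clone 3 replicate 1, 2 or 3, 1030 in a fit of only the 2 groups, 1384 with the length offset and 5587 without clone 2 replicate 3 and clone 4 replicate 3.

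Between clone 4 and the others, inflammatory genes were among the largest differences. Against clone 2, CCL20 (−9.03, adjusted p = 3.93e-10), TENM2 (−8.04), IL1A (−7.90), CXCL1 (−6.93) and IL1B (−6.30) were lowest in clone 4 on the log2 scale among genes that reach 5 CPM in either clone. Against clone 3, IL13RA2 (−9.45), SERPINB2 (−9.14 ± 0.59, adjusted p = 1.99e-07), CCL20 (−9.05), IL1A (−8.72) and CXCL1 (−8.34) were lowest by the same rule. SERPINB2 lay at 2.25 CPM in clone 4 replicate 3 and at 0.325 and 0.309 CPM in the others of clone 4, and without that library and clone 2 replicate 3 it differed from clone 3 by −10.67. IL13RA2 then differed from clone 3 by −10.34, and by −8.71 without clone 4 replicate 2 alone, and IL1B differed from clone 2 by −6.94. NF-κB targets were lower in clone 4 than in clone 2 in 24 of 26 cases and higher in none (25 and 0 adjusted over the list alone), with adjusted p = 2.68e-90, and adjusted p = 0.000185 with an estimated correlation. Against clone 3 they were lower in 24 of 26 cases and higher in none (25 and 0 adjusted over the list alone), with adjusted p = 5.08e-96, and adjusted p = 0.000172 with an estimated correlation. STS, steroid sulfatase, was higher in clone 4 than in clone 2 by 5.42 (0.152 against 5.53 CPM, adjusted p = 6.75e-06). Clone 3 held 0 reads of it against 790 in clone 4, at least 263-fold higher with a floor of 3 counts over the group. TNFRSF8, a TNF receptor family member (4.05 against clone 2 and 5.67 against clone 3), and ATP10A (4.11 and 5.43) were higher in clone 4 than in either. So were TCEA3 (3.60) and ZNF492 (3.26) against clone 2, and KRT17 (4.87, adjusted p = 7.46e-05, and 4.26 without clone 4 replicate 3) and CPA4 (4.38) against clone 3. ABCB1 was higher in clone 4 by 1.38 against clone 2 (adjusted p = 5.61e-06) and by 1.72 against clone 3 (adjusted p = 4.73e-07).

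By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 5825 genes differed between clones 4 and 2 (3025 higher, 2800 lower in clone 4), 1335 of them by at least 2-fold (446 higher, 889 lower). Between clones 4 and 3, 6523 genes differed (3489 higher, 3034 lower), 1567 by at least 2-fold (662 higher, 905 lower). The first count was 2943 in a fit of only the 2 groups.

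Neighbouring genes shifted together in parts of the genome. The settings for this description were chosen after window medians had been seen. Of 245 windows of 10 Mb that hold at least 15 of 9907 genes, 30, 32 and 28 had a median log2 change against the parent of at least 0.25 in size in clones 2, 3 and 4. On chromosome 3 from 30 to 60 Mb the median over 185 genes was −0.51 in clone 2 and −0.46 in clone 3. On chromosome 8 from 50 to 110 Mb it was −0.61 in clone 3 and −0.34 in clone 4 over 125 genes, and on chromosome 5 from 110 to 170 Mb −0.33 in clone 3 over 207 genes. In clone 4 it was 0.49 on chromosome 2 from 0 to 50 Mb (149 genes), 0.52 on chromosome 6 from 120 to 160 Mb (107 genes) and −0.49 on chromosome 7 from 130 to 160 Mb (94 genes). Of the shifted windows, 15 were shared by clones 2 and 3, 7 by clones 2 and 4 and 8 by clones 3 and 4, all in the same direction. The comparisons share the parent libraries, and no chance value was computed for these overlaps. All window counts include, for each clone, the window of chromosome 6 from 20 to 30 Mb that holds the histone genes. Its 36 genes that are not histone genes had medians of 0.15, 0.07 and 0.01 in clones 2, 3 and 4, and without the histone genes it would not pass 0.25.

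Several of the genes named above lie in such windows. CCNB1, CDC25C, KIF20A and TGFBI lie in windows of chromosome 5 that were lower in clone 3, and TMEM158, IL17RB, TNNC1, CDC25A and UQCRC1 in windows of chromosome 3 that were lower in clones 2 and 3. COX6C and UQCRB lie in a window of chromosome 8 with medians of −0.27, −0.64 and −0.38, and ANXA8 and ANXA8L1 in a window of chromosome 10 with medians of −0.31, −0.82 and −0.29. CXCL1 and CXCL5 lie in a window of chromosome 4 with a median of −0.57 in clone 4, and ARFGEF3, CTGF and SOD2 in windows of chromosome 6 that were higher in clone 4. BIRC5 and TK1 lie in a window of chromosome 17 with medians of −0.29 in clone 2 and −0.51 in clone 4. E2F2, MYOM3 and TCEA3 lie in a window of chromosome 1 with medians of −0.40 in clone 2 and −0.45 in clone 3.

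**Figure D4:**
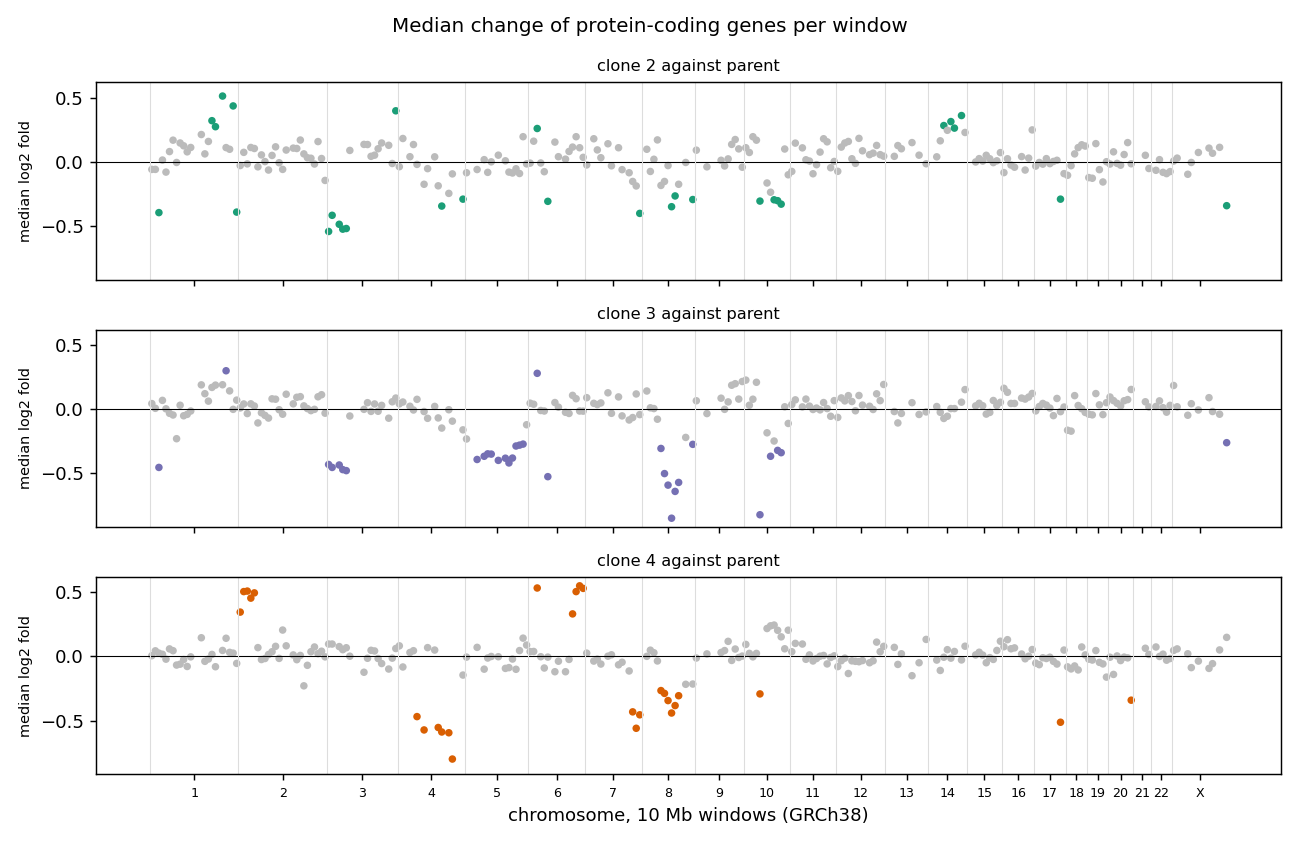
Median log2 change against the parent in windows of 10 Mb along the chromosomes, in a panel for each clone, with coloured points for medians of at least 0.25 in size. Clones 2, 3 and 4 show 30, 32 and 28 such windows.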

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

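The tests on rRNA, on a wrong label, the split by source of the first test of mixed cells and the later test of them were chosen only after the results had been seen.

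Clone 2 replicate 3 drew attention because 71% of its reads fell on FP671120.3 (chromosome 21, 8210384 to 8211306) and another gene with 18S rRNA sequence, a signal outside the genes compared. Lower depth alone was tested by thinning clone 2 replicate 1 to the protein-coding depth of replicate 3. The spread of log2 differences from replicate 2 was then 0.178, against 0.477 observed for replicate 3 over 12213 genes, a ratio of 0.374, so depth alone is argued against. A candidate explanation is rRNA that the depletion left behind, since mitochondrial rRNA, which belongs to another genome, stood at 11400 CPM of the protein-coding reads, 50 times the highest of the other 11 libraries. The mitochondrial mRNAs of that library were a median of 14.9 times the highest other library, with MT-ND1 at 36.1 times and MT-CO1 at 2.53 times, and for them rRNA left behind cannot be told apart from another cause, since their log2 levels were more uneven in the others (SD of at least 2.53, against 1.46) and the depletion may have removed some of them there. No biological explanation was tested, since the design gives none for a single culture.

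Clone 4 replicate 3 departed from its group in the direction of clone 2 replicate 3, with a correlation of departures of 0.422 across 10963 genes, which are not independent. Its reads on the 2 genes with 18S sequence were 0.00292% of the total, which argues against rRNA left behind, and its correlation with the other clone 4 libraries was 0.9877, against 0.9684 with the parent, the highest of the other groups, which argues against a wrong label. Cells of clones 2 or 3 are argued against, since genes of these clones gave median shares of 0.377% and 0.429%, where mixing needs 50%, while cells of the parent cannot be told apart from a change within clone 4 by this test, which gave 24.5% from 2 genes, too few. The later test argues against cells of any group as the main cause. At most 29% of the 62 genes that were 2-fold apart lay between the levels of clone 4 and a source, below the 80% set for mixing. This test cannot exclude mixing beside another change. The departure of clone 2 replicate 3 also correlated with that of replicate 3 of the parent (0.35) and of clone 3 (0.129). With replicate 1 of the parent and of clones 3 and 4 it stood at 0.031, 0.231 and −0.284, and with their replicate 2 at −0.308 to −0.388. The departure of clone 4 replicate 3 correlated at 0.165 and 0.247 with replicate 3 of the parent and of clone 3. With replicate 1 of the parent and of clones 2 and 3 it stood at 0.092, −0.415 and −0.068, and with their replicate 2 at −0.21, −0.387 and −0.232. A departure is taken from the other 2 libraries of the group, so the departures within a group cancel out. Values for clones 2 and 4 thus partly restate the 0.422. Stress genes under ATF4 were low and mitosis genes high in both libraries (medians of −0.81 and −0.49, and of 0.41 and 0.38). Neither a cause shared across groups, for which the labels give no batch, nor a biological one was tested.

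Between clones, 16 of the 64 genes named outside the lists and the NF-κB list drew attention because 2 clones differed from the parent in opposite directions and the test between those clones passed as well. That test is nearly bound to pass in such a case and adds no support. Apart from the 11 always named, the genes were picked for large changes in these same comparisons. Over all genes called in both clones, 464 of 1442 moved in opposite directions in clones 2 and 4. The counts were 591 of 1588 for clones 3 and 4 and 46 of 2515 for clones 2 and 3. For ABCB1 the log2 difference was 1.38 between clone 4 and clone 2 and 1.72 between clone 4 and clone 3. For inflammatory genes the differences of clone 4 from clones 2 and 3 were −7.90 and −8.72 for IL1A, −6.30 and −8.05 for IL1B, −6.93 and −8.34 for CXCL1, −9.03 and −9.05 for CCL20, and −5.31 and −6.20 for CXCL5, with medians of −2.27 and −3.19 over the NF-κB list. For SERPINB2 they were −5.38 and −9.14, for DCDC2 −5.91 and −3.25, for GALC −2.33 and −6.02, for ATP10A 4.11 and 5.43, for TNFRSF8 4.05 and 5.67 and for ZNF492 3.26 and 2.65. TENM2 and NEURL1 differed between clone 4 and clone 2 by −8.04 and −4.69 and between clone 3 and clone 2 by −4.88 and −3.39. CPA4 differed by −1.75 between clone 3 and clone 2 and by 4.38 between clone 4 and clone 3, and KRT17 by 4.87 between clone 4 and clone 3. Without clone 2 replicate 3 and clone 4 replicate 3 the values for SERPINB2 were −6.43 and −10.67, and those for IL1B against clone 2 and KRT17 against clone 3 were −6.94 and 4.24.

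Other groupings of the same libraries were fitted to see how many genes they call. For each pair of groups there are 10 splits, too few for a share under 0.05: the real counts were 4131, 4957, 3578, 2551, 5825 and 6523, the highest of the other splits called 0, and 1 of the 10 splits, the real grouping, was as large. For the 628 shared genes, 1 of 100 regroupings of the 12 libraries, the real grouping, was as large and the highest other gave 203. For the 3849 genes of the mean of the clones the highest other gave 1824, and the median of the others was 0 for both. This argues against a random division of the 12 libraries. Cultures of a group resemble each other, so the regroupings cannot show whether other clones would share as many changes. Chance differences between clones are not excluded. For the 13 lists a random division cannot be excluded, since 11 of 100 regroupings gave as many, with 15 as the highest other and a median of 9 over the others.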

How the results depend on the processing

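The fits without clone 2 replicate 3 and clone 4 replicate 3, and without the genes that took most reads of clone 2 replicate 3, were chosen after the data were seen. Under DESeq2 size factors, the DESeq2 Wald test, no filter, protein-coding genes alone and summing per gene identifier, every count of genes stayed within 1.5 times its value, and DESeq2 factors moved the median log2 change by at most 0.0134 in size. Of the 629 calls of named genes, 620 were kept with DESeq2 factors, 622 with the Wald test, 609 with no filter and 504 with the length offset, where 124 were lost and 1 changed sign. Without parent replicate 1, 2 or 3, 118, 110 and 100 of 599 were lost, and 31 of 467 in a fit of only the groups compared. A 2-fold minimum, which calls fewer genes by construction, left 773, 1080 and 795 genes for clones 2, 3 and 4 against the parent, 376, 1335 and 1567 for clone 3 against 2, 4 against 2 and 4 against 3, 486 for the mean of the clones and 106 for the shared genes. A fit of only the groups compared gave 2707 for clone 2 and 8682 for clone 3 against the parent, 1030 for clone 3 against 2 and 2943 for clone 4 against 2, and the length offset gave 1384 for clone 3 against 2 and 375 shared genes, and the cause was not tested. Leaving out 1 library at a time gave 2613 to 5404, 3553 to 3815 and 2438 to 3244 genes for clones 2, 3 and 4 against the parent, 1394 to 3621, 4574 to 7166 and 5164 to 6119 for clone 3 against 2, 4 against 2 and 4 against 3, 2201 to 5702 for the mean, 341 to 1092 shared genes and 11 to 15 lists. Where a group was left with 2 libraries it was assumed to vary like the others. Without clone 2 replicate 3 and clone 4 replicate 3 the counts were 7175, 8629 and 6301 against the parent, 5587, 7694 and 9129 between clones, 7284 for the mean, 1591 shared genes and 14 lists, with those of Wee1 and CDK1 control, TGFβ targets and cholesterol synthesis gained and those of MAPK output and early genes lost. The cause of the higher counts was not tested by itself, and 628 of the 629 named calls were kept. The comparison of clone 3 with the parent holds neither library, yet its count rose from 4957 to 8629, against 8682 with only the 2 groups. That rise came through what a fit shares between groups, such as its estimate of spread. Departures from the group had an SD of 0.588 in clone 2 replicate 3 and 0.269 in clone 4 replicate 3. In the parent and clone 3 it was 0.108 to 0.144. Without the dominating genes the counts were 4081, 5017, 3577, 2494, 5711 and 6532, with 3873 for the mean, 628 shared genes and 13 lists. Of the 13 lists, 2 were called with an estimated correlation, those of NF-κB targets and fibroblast markers (adjusted p of 0.0416 and 0.0916 without the 2 libraries), and fry called 18 but not those of mitosis (adjusted p = 0.114) and ATF4 (adjusted p = 0.152). With the length offset the sign turned for IFITM1 in clone 2 (−0.0374, adjusted p = 0.967) and in the mean for CDC25A (0.0239, adjusted p = 0.912) and CHEK1 (−5.46e-05, adjusted p = 1), and the cause was not tested. Lists were not run with the Wald test, the 2-fold minimum, the fits of only the groups compared or per gene identifier. With the library sizes and the spread of the fit of all 12 libraries, 40.3% of simulated log2 changes of 0.5 were recovered for clone 3 against the parent. Changes of that size that were not called are thus not shown to be absent.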

Other observations

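The choice of window settings came after the window medians had been seen, and the tests of chance placing, of single genes, of clone 2 replicate 3 and of copy number were chosen before their results.

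Single genes of lists that did not pass the test in the mean of the clones differed between clones and parent. ALDH1A3, a retinaldehyde dehydrogenase, lay at 37.2 CPM in the parent, 165 and 209 CPM in clones 2 and 3 (log2 changes of 2.14 and 2.49) and 18.7 CPM in clone 4 (−0.99, adjusted p = 0.00754). Of 15 drug metabolism genes, which include it, 3 rose and none fell in the mean of the clones (3 adjusted over the list alone, adjusted p = 0.416). The receptor tyrosine kinase ROR1 rose in each clone (1.21, 1.40 and 1.66) and FLT1, a VEGF receptor, in clones 3 and 4 (1.72 and 1.60), while of 25 such receptors 5 rose and 4 fell in the mean (5 and 5 adjusted over the list alone, adjusted p = 0.723). SC5D, an enzyme of cholesterol synthesis, rose in clones 2 (2.53, adjusted p = 3.9e-06) and 3 (2.05, adjusted p = 9.31e-06) and fell in clone 4 (−2.19, adjusted p = 0.00015). Of 25 cholesterol genes 1 rose and none fell in the mean (1 adjusted over the list alone, adjusted p = 0.473). In clone 2 replicate 3, 24 of 24 such genes with at least 5 CPM lay below the other libraries of the clone (median −0.94), and in clone 4 replicate 3, 23 of 24 did (−0.37). Without both libraries 14 rose in the mean (adjusted p = 0.00335, and adjusted p = 0.763 with an estimated correlation) and 22 in clone 2 (adjusted p = 5.88e-15, and adjusted p = 0.283 with an estimated correlation). OAS3 and IFIH1, sensors of viral RNA, rose in clones 2 (1.83 and 1.2) and 3 (1.81 and 1.65), and of 32 interferon-stimulated genes 5 rose and 2 fell in the mean (5 and 2 adjusted over the list alone, adjusted p = 0.309). Other members moved otherwise. Without clone 2 replicate 3 and clone 4 replicate 3, 9 rose and 9 fell in clone 2, 10 and 10 in clone 3, and 11 and 3 in clone 4. The list did not pass by camera in any of them (adjusted p of 0.997, 0.817 and 0.0922).

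Lists of DNA repair genes did not pass the test in the mean of the clones. Of 28 replication stress genes 2 rose and 6 fell (2 and 6 adjusted over the list alone, adjusted p = 0.931), with a median above 0 and a mean and test below it, and of 30 genes of homologous recombination and the Fanconi pathway 1 rose and 2 fell (1 and 2 adjusted over the list alone, adjusted p = 0.309). NBN, a part of the break-sensing MRN complex, fell in clones 3 and 4 (−0.78 and −0.62). Of 27 p53 targets 7 rose and 3 fell (8 and 3 adjusted over the list alone, adjusted p = 0.37), such as BTG2 (0.79, adjusted p = 0.00169) and the ferredoxin reductase gene FDXR (−0.49, adjusted p = 0.00263). Of 13 ABC transporters 1 rose and 2 fell (1 and 3 adjusted over the list alone, adjusted p = 0.42), with ABCB4 at −1.05 (adjusted p = 0.000386). Mitochondrially encoded mRNAs lay lower in 11 libraries than in clone 2 replicate 3. MT-CO1 stood at 556 to 813 against 2050 and MT-ND1 at 5.2 to 12.7 against 457 CPM of the protein-coding reads, and the reason was not tested.

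Neighbouring genes shifted together in the windows of 10 Mb described for the 3 clones. Chance placing of changed genes is argued against, since 0 of 1000 shuffles of gene positions gave as many shifted windows in any clone and the highest gave 2, 3 and 1. A few strong genes are argued against, since of genes held out from the choice of windows at least 86.7% moved in the direction of their window, and clone 2 replicate 3 is argued against, since 26 of the 30 windows of clone 2 were shifted the same way without it. A candidate explanation is a change in DNA copy number, a hypothesis of its own that no DNA data here can test: it needs genes of high and low expression to shift alike, and their medians differed by at most 0.04 (0.34 and 0.32 in clone 2, 0.38 and 0.35 in clone 3, 0.49 and 0.45 in clone 4). The histone window of chromosome 6, shifted in each clone, owes this to the histone genes and is no case for it, and other changes that cover whole regions, such as chromatin state, were not tested.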
